A study of Mus musculus with 6 samples.

How the data were processed

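Heart RNA of Rbpms knockout and wildtype mice, 3 libraries each, was sequenced as stranded mRNA libraries with single-end reads, per the labels' protocols. Per the submitters' processing notes, which give neither role nor order, the authors' tools included Trimmomatic 0.39, STAR 2.7.11a, Picard 3.0.0, featureCounts 2.0.4 and DESeq2 1.36.0, with the genome build mm39. The deposited values are treated as a score: whole numbers that the authors made by multiplying the reads of a gene by a factor for each library and rounding. This was read from the values, because certain whole numbers never occurred at regular steps in 3 libraries and occurred doubly often at regular steps in the other 3. The setting of strand in the authors' read counting and any filter on low values are not given in the sources used here. Picard can mark duplicate reads, but the notes do not say for what it was used.

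The factors were estimated from the spacing of the low values, those under 400, as 0.9371, 1.0384 and 0.8524 in knockout replicates 1, 2 and 3 and 1.0423, 0.9568 and 1.1798 in wildtype replicates 1, 2 and 3. Dividing by them recovered 5244631, 4773244, 5805783, 4655117, 5060232 and 4163230 reads in the same order. The factors were refined to make the share of values that a whole read number gives after rounding as high as possible. That share was 100%, which tests only the libraries with factors above 1. In the libraries with factors under 1, 11.46%, 30.12% and 7.01% of the values (knockout replicates 1 and 3, wildtype replicate 2) could come from more than 1 read number. At this depth a gene with a value of 10 rests on about 10 reads.

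The count test, its replacement for normalized values, the gene lists and the rule for named genes were fixed before the data were examined. Since the values were not raw counts, the count test was not used and the replacement took its place. This was limma 3.58.1 (with statmod 1.5.0) in R 4.3.3 on log2(value + 1), with an intensity trend and robust moderation, on all 6 libraries and with no covariate. Genes with a value of at least 10 in at least 3 libraries were tested, 14974 of 20893, a filter set after the values were read and before any test was run. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Values are means ± SD over the 3 libraries of a group.

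Of the 32 gene lists, those to be tested that had at least 5 tested genes, 27 in all, were compared with all other genes by camera with a preset correlation of 0.01. None of the 7 lists called in this way was called with an estimated correlation or by the directional test of fry, a rotation test of the list's own genes. The mixed test of fry, which allows changes in both directions, passed 2 of the 7, p53 targets (adjusted p = 0.000579) and calcium handling (0.0409). It also passed the compact myocardium (0.00321), fetal and stress (0.00899) and neural lists (0.0327). The estimated correlation and fry were run on all 6 libraries with no further term, so calls that other fits added were not tested in these 2 ways within those fits. Counts within a list were also adjusted over the list alone. Shares of the total were compared by two-sided exact permutation tests over 5 measures, unadjusted, with a smallest p of 0.1.

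By the rule for named genes, Rbpms and Rbpms2 were always named, followed by the 10 largest rises and the 10 largest falls. These came from genes with an adjusted p under 0.05, a mean CPM of at least 1, groups that do not overlap and a symbol that is not a predicted name, with sex-linked genes left out. Then came up to 4 changed members of each list by smallest p, or the member with the smallest p where none changed. Gene symbols, identifiers and coordinates are those of the deposited table, in which 8 symbols occurred more than once.

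The scripts were tested on simulated data for the comparison of knockout and wildtype, with 14955 genes tested. They called 50.7% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 83.3% of those changed 4-fold, 100% of them with the true sign, and 11 of 141 calls were false (7.8%). In a second simulated data set only the genes of the mitosis list were raised. There the raised list was found, 0 of the other lists was called and 0 genes outside the raised list were called. Genes were simulated independently of each other, so this does not test the preset correlation of camera. All libraries were drawn with the same spread, so the shares called and false do not cover a library that stands apart, as knockout replicate 3 did. In the real data the estimated correlation was 0.53 in the DNA replication list and 0.95 in the mitosis list.

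Exon length and GC content came from another annotation, of the build GRCm38, matched by gene identifier for 98.2% of the tested genes, and none of its coordinates were used. Alternatives covered scaling, filter, pseudocount, moderation, voom, thresholds, a term for sex, the replicate number as a block, sample weights, male libraries only and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the recovery of reads, summaries and figures.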

Results

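Gene expression was measured by sequencing of stranded mRNA libraries from mouse hearts, 3 libraries with a germline knockout of Rbpms and 3 wildtype libraries. The comparison asks how the heart transcriptome differs without this gene. Rbpms encodes an RNA-binding protein with a single RNA recognition motif, and Rbpms2 is its closest paralogue. The series title calls the hearts embryonic and its design text calls them neonatal, and the stage was not resolved here. The design text also names the controls as littermates. The table held 20893 genes on 21 chromosomes, of which 15438 were protein coding and 3420 were long noncoding RNA genes. Each value was a read number multiplied by a factor for its library and rounded. The read totals recovered from these factors ran from 4163230 to 5805783. A value of at least 10 in at least 3 libraries was reached by 14974 genes, and these were tested. Nothing in the descriptions used here states that each library came from a separate animal, so the p-values measure only the spread between these samples.

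Rbpms was lower in every knockout library. It lies on chromosome 8, from 34272671 to 34419891 on the reverse strand of mm39. Its value was 407 ± 88.1 (SD, n = 3) in knockout and 1220 ± 79.7 (SD, n = 3) in wildtype hearts. The knockout libraries held 375, 340 and 507, and the wildtype libraries 1182, 1176 and 1317. Its log2 fold change was -1.61 with a standard error of 0.14 (limma, adjusted p = 0.0124), which is 0.329 of the wildtype level. Rbpms2 held 516 ± 26.1 against 546 ± 33.8 (SD, n = 3 each). Its log2 fold change was -0.08 with a standard error of 0.07 (limma, adjusted p = 0.627). Reads on Rbpms remained in the knockout, and the deleted part of the gene is not given in the sources used here. Its adjusted p rose to 0.0523 without knockout replicate 1 and to 0.0868, 0.0967 and 0.133 without wildtype replicates 1, 2 and 3, within 2.65e-08 to 0.21 over 22 alternatives.

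Among the genes with the largest rise in knockout hearts were Xirp2, an actin-binding protein of the intercalated disc, and Mybpc2, the fast skeletal form of myosin-binding protein C. Xirp2 rose from 151 ± 28.7 to 485 ± 122 (SD, n = 3 each), a log2 fold change of 1.67 (limma, adjusted p = 0.0239). Mybpc2 rose from 93.7 ± 6.66 to 250 ± 47.3 (log2 1.39, adjusted p = 0.0124). The keratins Krt80 and Krt8 rose from 71 ± 16 to 332 ± 123 and from 32.7 ± 2.08 to 87 ± 7.94. Their log2 fold changes were 2.17 and 1.38 (adjusted p = 0.0242 and 0.0202). Psca, a cell surface protein anchored by a lipid, had the highest fitted rise of the named genes, from 3 ± 1 to 32.3 ± 11.6 (log2 3.02, adjusted p = 0.0214). Prg4, the joint lubricant lubricin, rose by a log2 fold change of 1.33 (adjusted p = 0.0202). Slc9a3, a sodium and proton exchanger (1.75), and Btnl12, a butyrophilin-like gene (1.72), rose with adjusted p = 0.0498 and 0.0225. Calhm5, of a calcium homeostasis modulator family (1.34), and Hmcn2, a hemicentin of the extracellular matrix (1.25), rose with adjusted p = 0.0379 and 0.0472.

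The deepest falls included Kcnd2, which encodes a potassium channel subunit of the transient outward current, and Ces1d, a carboxylesterase. Kcnd2 fell from 115 ± 17.2 to 22.7 ± 7.37 (SD, n = 3 each), a log2 fold change of -2.33 (limma, adjusted p = 0.0124). Ces1d fell from 63.7 ± 28.4 to 3.33 ± 2.52 (log2 -3.96, adjusted p = 0.0225). It belongs to a family of similar genes, so reads shared with a copy leave its value uncertain. Wdr72 fell from 82.7 ± 6.66 to 18.7 ± 1.53 (log2 -2.09, adjusted p = 0.0101). Ddit4l, an inhibitor of mTOR signalling, fell from 91.3 ± 30.1 to 21.7 ± 5.51 (log2 -2.01, adjusted p = 0.022). Ppp1r1b and Arpp21, phosphoproteins regulated by cyclic AMP, fell from 241 ± 12.2 to 75.7 ± 23.6 and from 45.7 ± 10.1 to 14 ± 2.65. Their log2 fold changes were -1.71 and -1.63 (adjusted p = 0.0221 and 0.0356). Arhgap36 (-1.98) and the adaptor Grap2 (-1.97) fell with adjusted p = 0.0307 and 0.0472. Gadl1 (-1.82) and the zinc finger gene Zfand4 (-1.69) fell with adjusted p = 0.0494 and 0.0159.

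**Figure D1:**
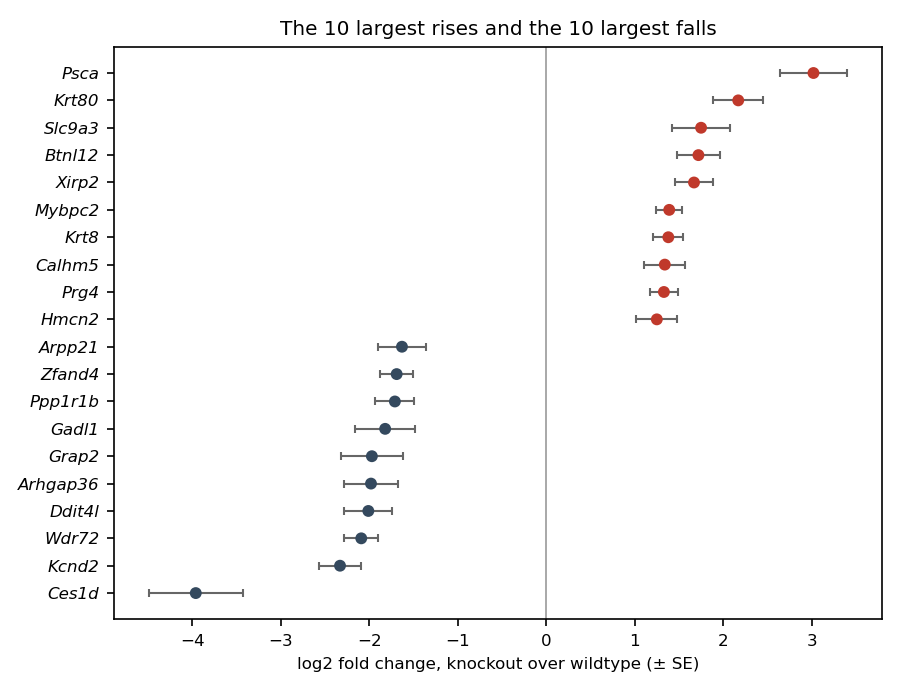
The log2 fold change of knockout over wildtype hearts (horizontal axis) of the 10 genes with the largest rise (red) and the 10 with the largest fall (dark) among the changed genes that met the naming rule, with bars of 1 standard error. The values run from -3.96 for Ces1d to 3.02 for Psca.

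In all, 141 of 14974 genes changed, 76 higher and 65 lower in knockout hearts (limma on log2(value + 1), Benjamini-Hochberg adjusted p under 0.05). Cavin4, a caveolar protein of muscle, had the smallest p of all genes and was singled out after its values were seen. It rose from 352 ± 13.9 to 657 ± 41.6 (SD, n = 3 each; log2 0.9, adjusted p = 0.00789). Of the changed genes 129 were protein coding and 12 long noncoding. More than 2-fold changes were seen in 20 higher and 32 lower genes, and the median absolute log2 fold change was 0.83. An unadjusted p under 0.05 was reached by 2456 genes where chance gives 749 on average. The groups did not overlap in 3291 genes, 22% where chance gives 10% on average. Genes move together, so a single split can depart widely from these averages, and other splits were not counted in these 2 ways. With voom on the same values 72 genes changed, 38.9% of them higher, against 53.9% in the test above. The count was 6, 510 and 727 without knockout replicates 1, 2 and 3. It was 3 without wildtype replicate 1 and 0 without wildtype replicate 2 or 3, where limma gave 2176 and 1852 genes at an unadjusted p under 0.05. Without knockout replicates 1, 2 and 3, 1, 10 and 10 of the 10 named rises and 3, 10 and 10 of the 10 named falls stayed past the threshold. Without wildtype replicates 1, 2 and 3 these numbers were 1, 0 and 0 for the rises and 0, 0 and 0 for the falls.

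**Figure D2:**
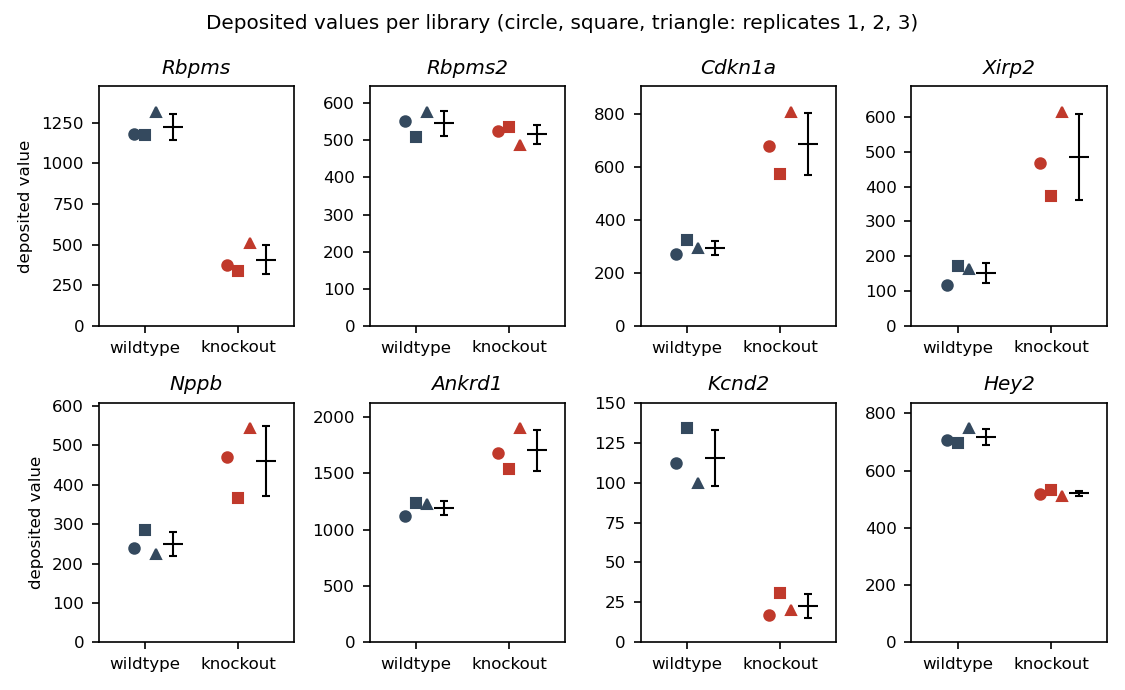
Deposited values (vertical axis, from 0) of 8 genes in the 3 wildtype (dark) and 3 knockout (red) libraries, with a point per library and the mean ± SD at the right of each group. The groups of Rbpms, Cdkn1a, Xirp2, Nppb, Ankrd1, Kcnd2 and Hey2 do not overlap, and those of Rbpms2 (516 and 546 on average) do.

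Among 20 tested genes of the fetal programme and wall stress of cardiomyocytes, 3 rose and 0 fell, and 5 rose when adjusted over the list alone. The 3 were Xirp2, given above, Nppb and Ankrd1. Nppb, which encodes the B-type natriuretic peptide, rose from 250 ± 31.4 to 460 ± 89 (SD, n = 3 each; log2 0.87, adjusted p = 0.0472). Ankrd1, a stretch-responsive ankyrin repeat protein, rose from 1190 ± 61.8 to 1700 ± 182 (log2 0.51, adjusted p = 0.0372). The list as a whole did not pass (camera, adjusted p = 0.068). It was called higher without knockout replicate 1 (0.0303) and wildtype replicate 3 (0.0205) and by voom on recovered reads (0.0478), and had an adjusted p = 0.885 with an estimated correlation. In it 4 genes rose without knockout replicate 3, and 0 without knockout replicate 1 or each wildtype replicate in turn. Of its members 3 lay above 0.5 recovered reads per base of exon, the highest of them Nppa at 0.853. Of 32 tested genes of calcium handling and ion channels, Kcnd2 fell and Itpr2, an inositol trisphosphate receptor, rose from 383 ± 45.8 to 569 ± 50.9 (log2 0.57, adjusted p = 0.0472). In that list 2 rose and 3 fell adjusted over the list alone, and 23 had a fold change below 0. It was called lower (camera, adjusted p = 0.0426), with a median log2 fold change of -0.13, and had an adjusted p = 0.976 with an estimated correlation. Its adjusted p was 0.357 without knockout replicate 3, 0.163 without wildtype replicate 3 and 0.292 in male libraries only. It held 2 risen and 3 fallen genes without knockout replicate 2, 0 and 1 without knockout replicate 1, and 0 and 0 without each wildtype replicate in turn. Hey2, a Notch-responsive repressor of compact myocardium, fell from 717 ± 27.4 to 521 ± 9.29 (log2 -0.46, adjusted p = 0.0219). It was the 1 changed gene of 14 in its list, also when adjusted over the list alone (camera, adjusted p = 0.469).

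By limma 0 of 25 sarcomere genes, which build the contractile apparatus, changed, with 0 adjusted over the list alone, 0 by voom on recovered reads and 3 at an unadjusted p under 0.05. Their median log2 fold change was -0.04 (camera, adjusted p = 0.891). The slow myosin Myh7 had the smallest p among them, at 4800 ± 219 against 4020 ± 107 (SD, n = 3 each; log2 0.25, adjusted p = 0.0901). Without knockout replicate 3, 1 sarcomere gene rose. Myh7, Ankrd1 and Nppb averaged 0.518, 0.514 and 0.471 recovered reads per base of exon, and the mean of no gene passed 1. Above 0.5 lay 12 of the 25 sarcomere genes, with Mybpc3, Actc1, Myh6 and Tnnc1 at 0.925, 0.919, 0.792 and 0.755. A count of 0 among genes this close to 1 is no measure of stability. Among the 13 at or under 0.5, limma gave 0 changed genes, 2 at an unadjusted p under 0.05 and a median log2 fold change of 0.03. In the trabecular list 0 of 15 genes changed by limma or voom (3 at an unadjusted p under 0.05), and 1 rose when adjusted over the list alone. The growth factor Nrg1 stood there at 74.7 ± 48.4 against 15.7 ± 2.31 (log2 2.01, adjusted p = 0.0601), and the list was not called (camera, adjusted p = 0.615). In this list 4 genes rose without knockout replicate 3, 4 in male libraries only, 1 without knockout replicate 2 and 1 with a term for sex. Of 29 cardiac transcription factors 0 changed by limma or voom (3 at an unadjusted p under 0.05), and 1 fell when adjusted over the list alone. That list was not called (camera, adjusted p = 0.99), and 1 of its genes rose without knockout replicate 3.

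DNA replication genes were lower in knockout hearts as a list (camera, adjusted p = 1.97e-13), with all 26 tested fold changes below 0 and a median log2 fold change of -0.51. The list had an adjusted p = 0.741 with an estimated correlation, within 2.86e-18 to 0.741 over 14 alternatives. Pola1, the catalytic subunit of DNA polymerase alpha, fell from 110 ± 8.72 to 60.3 ± 7.37 (SD, n = 3 each; log2 -0.86, adjusted p = 0.0472). No other member passed over all genes, while 19 fell and 0 rose when adjusted over the list alone. Over all genes 0, 13 and 4 members fell without knockout replicates 1, 2 and 3, and 0 without each wildtype replicate in turn. Adjusted over the list alone these numbers were 2, 25 and 10, and 0, 17 and 0 without wildtype replicates 1, 2 and 3. The knockout libraries had list medians of -0.64, -0.21 and -0.77 against the wildtype mean. Cdkn1a, which encodes the p21 inhibitor of cyclin-dependent kinases, rose from 295 ± 26.1 to 685 ± 118 (log2 1.2, adjusted p = 0.0124). Zmat3, another p53 target, rose from 264 ± 27 to 408 ± 56.1 (log2 0.62, adjusted p = 0.0494). These were the 2 changed genes of 17 tested p53 targets and inhibitors of cyclin-dependent kinases, and 5 rose and 1 fell adjusted over the list alone. Risen genes numbered 0, 3 and 5 without knockout replicates 1, 2 and 3, with 1 fallen in the last case, and 0 without each wildtype replicate in turn. That list was called higher (camera, adjusted p = 0.00437) and had an adjusted p = 0.493 with an estimated correlation.

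Genes of mitosis were called lower as a list (camera, adjusted p = 0.000202), with 31 of 32 fold changes below 0 and a median of -0.39. The list had an adjusted p = 0.976 with an estimated correlation, which was 0.95, so its genes moved nearly as 1. By limma 0 of its genes changed, 0 adjusted over the list alone and 0 by voom on recovered reads, with 2 at an unadjusted p under 0.05. Aurkb, the aurora kinase of the chromosomal passenger complex, stood at 83.3 ± 20.8 against 134 ± 35.8 (SD, n = 3 each; log2 -0.67, adjusted p = 0.214). The knockout libraries differed, with list medians of -0.88 and -0.65 in replicates 1 and 2 and 0.36 in replicate 3. Without knockout replicate 3, 24 of the 32 genes fell, 31 adjusted over the list alone, with a median of -0.77 (camera with the preset correlation, adjusted p = 2.12e-29). That fit left out the 1 knockout library with a median above 0 and was not run with an estimated correlation. Without knockout replicate 1 the list was not called (adjusted p = 0.0669).

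**Figure D3:**
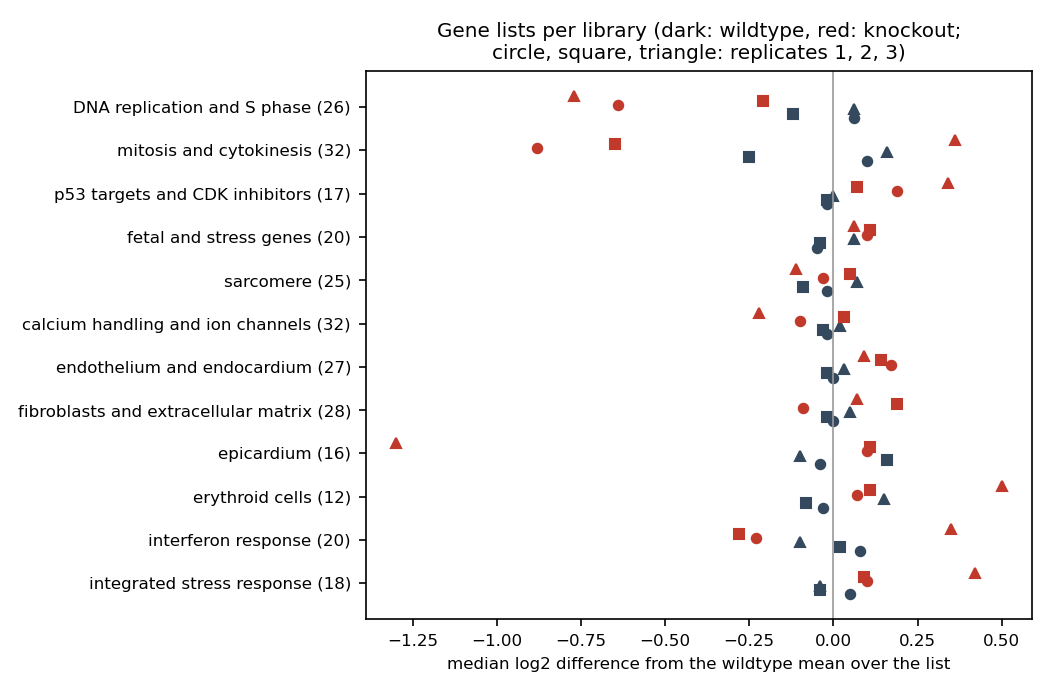
Median log2 difference from the wildtype mean (horizontal axis) over the genes of 12 lists in each of the 3 wildtype (dark) and 3 knockout (red) libraries, with the number of tested genes in brackets and a symbol per replicate. The mitosis list lies at -0.88, -0.65 and 0.36 in the 3 knockout libraries, and the epicardium list at 0.1, 0.11 and -1.3.

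Endothelial and endocardial genes were called higher (camera, adjusted p = 0.00124), with 22 of 27 fold changes above 0 and a median of 0.15. The list had an adjusted p = 0.493 with an estimated correlation. By limma 0 of its genes changed, and 0 by voom on recovered reads, with 9 higher and 1 lower at an unadjusted p under 0.05. Adjusted over the list alone, 1 rose, and over all genes 2 rose without knockout replicate 2 and 2 without knockout replicate 3. Emcn, an endothelial sialomucin, stood at 531 ± 56.4 against 399 ± 18.5 (SD, n = 3 each; log2 0.41, adjusted p = 0.0669). Erythroid genes were called higher as well (camera, adjusted p = 0.0497), with an adjusted p = 0.976 with an estimated correlation. Of 12 erythroid genes 0 changed by limma or voom or adjusted over the list alone, with 1 at an unadjusted p under 0.05. Their medians were 0.07, 0.11 and 0.5 in the 3 knockout libraries. Slc25a37, a mitochondrial iron importer, stood at 406 ± 73.7 against 316 ± 22.5 (log2 0.35, adjusted p = 0.206). The erythroid call was lost without knockout replicate 3 (adjusted p = 0.229), wildtype replicate 1 (0.0644) and wildtype replicate 2 (0.0895), and in male libraries only (0.345).

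In the epicardium list Krt8, given above, rose and 0 of 16 fell, with 2 risen adjusted over the list alone. The list's median was -0.35 (camera, adjusted p = 0.99), with library medians of 0.1, 0.11 and -1.3 in the knockout. Its count was 1 risen and 1 fallen without knockout replicate 2, 2 risen without knockout replicate 3 and 0 without knockout replicate 1 or each wildtype replicate in turn. Of 28 fibroblast and matrix genes 0 changed by limma or by voom on recovered reads (7 at an unadjusted p under 0.05), but 5 rose adjusted over the list alone (camera, adjusted p = 0.0707). The matricellular gene Ccn2 stood at 1260 ± 333 against 624 ± 51.6 (SD, n = 3 each; log2 0.99, adjusted p = 0.0615), with 0.344 recovered reads per base of exon. Without knockout replicate 2, 3 fibroblast and matrix genes rose and 1 fell, and 4 rose without knockout replicate 3, 3 with a term for sex and 3 in male libraries only. The list was called higher without knockout replicate 1 (adjusted p = 0.00075) and wildtype replicate 3 (0.0292), with a term for sex (0.0335) and with the replicate number as a block (0.0498). With an estimated correlation its adjusted p = 0.976. Of 27 smooth muscle genes 0 changed by limma or voom (7 at an unadjusted p under 0.05), and 1 rose and 5 fell adjusted over the list alone (camera, adjusted p = 0.99). The smooth muscle myosin Myh11 stood at 205 ± 29.7 against 310 ± 25.8 (log2 -0.61, adjusted p = 0.057), but it fell with a term for sex (0.0494), in male libraries only (0.0372) and without knockout replicates 2 and 3 (0.025 and 0.00951), within 0.000404 to 0.261 over 13 alternatives. Among 18 leukocyte genes 0 changed by limma or voom (4 at an unadjusted p under 0.05), and 3 rose adjusted over the list alone (camera, adjusted p = 0.0801). Lyve1, a hyaluronan receptor of resident macrophages and lymphatic vessels, stood at 494 ± 100 against 279 ± 37 (log2 0.81, adjusted p = 0.0657). In the leukocyte list 3 genes rose without knockout replicate 2, and the list was called higher there (adjusted p = 0.0179), without wildtype replicate 2 (0.0459) and with a mean CPM of at least 1 (0.041), with an adjusted p = 0.976 with an estimated correlation. Neural genes (0 of 10 changed, 3 at an unadjusted p under 0.05) and skeletal muscle genes (0 of 10 changed, 1 at an unadjusted p under 0.05) were not called (camera, adjusted p = 0.737 and 0.891). Adjusted over the list alone, 0 of either changed, and 2 and 1 neural genes fell without knockout replicates 2 and 3. The lists of lung, thymus and liver genes and of brown fat genes had 4 tested members each and no list test. In these 0 changed by limma or voom, 1 and 2 were at an unadjusted p under 0.05, and 0 and 1 changed adjusted over the list alone. Without knockout replicate 2, 1 gene of the lung, thymus and liver list rose.

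Of the lists on signalling and stress, the integrated stress response was called higher (camera, adjusted p = 0.0238) and had an adjusted p = 0.885 with an estimated correlation. Its amino acid transporter Slc7a5 rose from 308 ± 22.5 to 457 ± 58.8 (SD, n = 3 each; log2 0.56, adjusted p = 0.0498). It was the 1 changed gene of 18 tested, and 2 rose adjusted over the list alone. The knockout library medians were 0.1, 0.09 and 0.42, and the call was lost without knockout replicate 3 (adjusted p = 0.123), without wildtype replicate 2 (0.0522) and in male libraries only (0.0735). In it 2 genes rose without knockout replicate 2 and 2 without knockout replicate 3. Bmp5, a bone morphogenetic protein, fell from 101 ± 11.2 to 45.3 ± 11.1 (log2 -1.16, adjusted p = 0.0464). It was the 1 changed gene of 28 in TGF beta and BMP signalling, also when adjusted over the list alone (camera, adjusted p = 0.0787). That list was called higher without knockout replicate 1 (0.0133) and wildtype replicate 2 (0.0363), and 1 of its genes rose without knockout replicate 2. It had an adjusted p = 0.885 with an estimated correlation. Rbfox1, a splicing regulator, fell from 233 ± 30 to 125 ± 6.51 (log2 -0.88, adjusted p = 0.0219). Of the 29 RNA-binding and splicing regulators it was the 1 changed gene, with 1 risen and 1 fallen adjusted over the list alone (camera, adjusted p = 0.994), and 1 rose without knockout replicate 3. Immediate early genes and interferon response genes were not called (camera, adjusted p = 0.222 and 0.615). In each of these lists 0 of 20 changed by limma or voom or adjusted over the list alone, with 2 at an unadjusted p under 0.05. The interferon list had knockout medians of -0.23, -0.28 and 0.35. It was called lower without knockout replicate 3 (adjusted p = 0.0038), where 1 of its genes fell over all genes and 6 adjusted over the list alone, and in male libraries only (0.015), and had an adjusted p = 0.996 with an estimated correlation. The immediate early list had knockout medians of -0.18, -0.09 and 0.54 and was called higher without knockout replicate 1 (0.0133) and wildtype replicate 1 (0.0338), with an adjusted p = 0.976 with an estimated correlation. Of its genes 1 rose without knockout replicate 2, 1 without knockout replicate 3 and 1 in male libraries only.

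Aldoc, the brain form of the glycolytic enzyme aldolase, fell from 207 ± 28.9 to 106 ± 11.2 (SD, n = 3 each; log2 -0.95, adjusted p = 0.0233). It was the 1 changed gene of 21 glycolysis genes, also when adjusted over the list alone (camera, adjusted p = 0.132). Glycolysis was called lower without wildtype replicate 2 (0.00744) and had an adjusted p = 0.976 with an estimated correlation. Aldoc was also the 1 changed gene of 19 hypoxia genes, where 2 rose and 4 fell adjusted over the list alone (camera, adjusted p = 0.99). Hypoxia genes that fell numbered 3 without knockout replicate 2, where 2 rose, and 3 without knockout replicate 3. Nuclear genes of oxidative phosphorylation (36 tested), genes of fatty acid oxidation (28) and ribosomal protein genes (45) were not called (camera, adjusted p = 0.0879, 0.233 and 0.99). In these lists 0 genes changed by limma, by voom on recovered reads or adjusted over the list alone, with 0, 1 and 1 at an unadjusted p under 0.05. Without wildtype replicate 2 all 3 lists were called lower (adjusted p = 2.93e-05, 0.0227 and 0.0433). Oxidative phosphorylation was also called lower without knockout replicate 2 (0.0179) and by voom on recovered reads (0.0478), and fatty acid oxidation without knockout replicates 1 and 2 (0.0277 and 0.0373). Each of these 3 lists had an adjusted p = 0.996 with an estimated correlation. In these lists 9, 4 and 2 genes lay above 0.5 recovered reads per base of exon. The oxidative phosphorylation medians were -0.03, 0.03 and -0.13 in knockout replicates 1, 2 and 3 and 0.01, -0.13 and 0.12 in wildtype replicates 1, 2 and 3. In the same order the scaling factors were 0.9371, 1.0384, 0.8524, 1.0423, 0.9568 and 1.1798. Whether these calls depend on the depth of the libraries was not tested. The table held 0 genes of the mitochondrial genome, so these could not be analysed. Of 16 tested neighbours of Rbpms on chromosome 8, 0 changed by limma or voom (4 at an unadjusted p under 0.05), and 1, which was Nrg1, rose when adjusted over the list alone. Over all genes Nrg1 rose with a term for sex (adjusted p = 0.0208), in male libraries only (0.0249) and without knockout replicates 2 and 3 (0.0137 and 0.00752), within 0.000497 to 0.261 over 13 alternatives. Of the 14 changed genes named as members of lists, 1, 14 and 14 stayed past the threshold without knockout replicates 1, 2 and 3, and 0, 0 and 0 without wildtype replicates 1, 2 and 3.

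Knockout replicate 3 stood apart from the other libraries. The first principal component took 45.1% of the variance and placed it at -48.3, with knockout replicates 1 and 2 at -9.73 and 4.44 and the wildtype libraries at 18.1, 14.8 and 20.7. It differed by more than 2-fold from each other library in 256 genes, against 11 to 25 for the others. Xist and the Y-linked genes showed 1 female and 2 male libraries in each group, the females being knockout replicate 3 and wildtype replicate 1. Each group therefore came from more than 1 animal. All pairs of replicates within a group differed by more than read sampling alone gives. For the 2 male libraries of a group this does not tell separate animals from repeat libraries. The chi-square per degree of freedom was 1.45 to 2.82 among wildtype pairs and 2.3, 6.97 and 8.87 among knockout pairs. Erythroid genes took 0.0487% ± 0.0225 of the total in knockout and 0.0333% ± 0.00186 in wildtype hearts (SD, n = 3 each), with 0.0747% in knockout replicate 3. The two-sided exact permutation test gave p = 0.2, where 0.1 is the smallest that 3 against 3 allows.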

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

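Tests chosen after the data were seen were voom on recovered reads, sample weights, male libraries only, the term for sex in named genes and lists, that term with sample weights, and the counts within lists without each library in turn. The groups of all 141 changed genes do not overlap, so leaving out a library could not turn their direction, and such fits say nothing on it. Rbpms was at -1.77 to -1.49 without each library in turn. The number of changed genes depended on the setting, and the cause was not tested. Median-ratio scaling gave 141, but its factors ran only from 0.998 to 1.001. The deposited values were already nearly on that scale, so this fit is no independent check. A mean CPM of at least 1 gave 127, and pseudocounts of 0.1 and 5 gave 113 and 147. Upper quartile scaling gave 93 (44 higher), moderation that was not robust 90 (44 higher), and voom 72 (28 higher) on the deposited values and 73 (27 higher) on recovered reads. No filter on low values gave 218 (117 higher, 101 lower), with more genes tested. A term for sex gave 223 (122 higher, 101 lower), male libraries only 256 (125 and 131), sample weights 3486 (1728 and 1758) and a term for sex with sample weights 1257 (650 and 607). The sample weights were 3.45 and 3.29 for knockout replicate 1 and wildtype replicate 1 and 0.26 to 0.84 for the other 4 libraries, so that fit rests mostly on 1 library per group. An adjusted p under 0.01 left 1 gene, Cavin4 (1 higher, 0 lower), with Rbpms at -1.61 and adjusted p = 0.0124. Tested with limma against a fold of 1.5, 0 genes passed (0 higher, 0 lower, 176 at an unadjusted p under 0.05), with Rbpms at -1.61 and adjusted p = 0.21. Leaving out a library gave 0 to 727 changed genes, 0 to 338 higher and 0 to 389 lower, with 0 for wildtype replicate 2 or 3 (2176 and 1852 genes at an unadjusted p under 0.05) and 727 for knockout replicate 3.

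Gene lists called higher and lower, 4 and 3 with the preset correlation of camera, were 0 and 0 with an estimated correlation and 0 and 0 by the directional test of fry. Male libraries only gave 2 and 3, and leaving out a library gave 2 to 8 higher and 2 to 7 lower. The lists of DNA replication, p53 targets and endothelium stayed called without each library in turn. For single lists 329 values under alternatives kept their side of the threshold, 25 lost it and 24 gained it, and for named genes these numbers were 440, 174 and 36.

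The labels number replicates 1 to 3 in both groups without saying that a number marks a litter. The values showed no pairing by number: deviations of libraries with the same number correlated at -0.17, -0.11 and -0.13, and 0 of 3 had its best partner in its own number. With 3 libraries per group, of which knockout replicate 3 stood apart, this cannot exclude matched litters. With the replicate number as a block, 23 genes were called (12 higher, 11 lower), 20 of them among the 141. The planned quasi-likelihood test with its own scaling and filter and the planned Wald test were not run, because the values are not counts. The depth of 4163230 to 5805783 reads limits what low genes can show.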

Other observations

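Tests chosen only after the result was seen are those of sex in knockout replicate 3, of fewer endothelial cells and fibroblasts, of duplicate removal, of genes near Rbpms in other fits and of the spread of the age genes, and every pattern here was first noticed in these data.

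Genes that report the ERK pathway, which relays growth factor signals, were singled out after their values were seen. Etv5, Phlda1, Spry4 and Dusp6 rose in knockout hearts, with log2 fold changes of 1.05, 1.11, 0.7 and 0.47 (limma, adjusted p = 0.0214, 0.0202, 0.0219 and 0.0315). A higher output of this pathway may account for them, so 15 other targets were tested: their median log2 fold change was 0.16, 10 were above 0 and 0 changed by limma, with camera p = 0.00436 and p = 0.103 with an estimated correlation. The median lies between the bounds set for and against the hypothesis, which stays open.

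Targets of YAP, a coactivator that responds to stretch and cell contact, were tested because Ankrd1 rose and Ccn2 was higher. Their 18 other members had a median log2 fold change of 0.29, with 16 above 0 and 0 changed by limma. The list passed at p = 6.71e-06 with the preset correlation and had p = 0.137 with an estimated correlation, and the knockout libraries had medians of 0.15, 0.13 and 0.53. Higher YAP output may therefore be a candidate explanation, weakly held because the estimated correlation ends the call and knockout replicate 3 carries the highest median.

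The 141 changed genes compare with at most 0 in the other 9 splits of the 6 libraries into 3 and 3, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Alleles carried along beside Rbpms could also differ between the groups. Of 86 tested genes other than Rbpms within 10 Mb of it, 0 changed, where 0.804 were expected. With so small an expected number, this count could show only a large excess. The count was 1 with a term for sex and in male libraries only, 2 without knockout replicate 2, 3 without knockout replicate 3 (1.28, 1.46, 2.92 and 4.17 expected) and 19 with sample weights (20 expected). Nrg1 was among them in each of these 5 fits and stood at 54, 40 and 130 in the knockout and 17, 17 and 13 in the wildtype libraries (limma, adjusted p = 0.0601). Adam9 was among them without knockout replicate 2, without knockout replicate 3 and with sample weights, and Zdhhc2 in the last 2 of these. Carried alleles that act on single genes such as these therefore stay open.

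Knockout replicate 3 stood apart, with mitosis genes higher and epicardial genes lower than in the other knockouts. Across autosomal genes its deviation from the other knockouts correlated with that of the female wildtype library at r = -0.03, where genes are not independent replicates. This speaks against a sex difference shared by both groups, as far as 1 female library per group can show. A knockout effect found only in females cannot be told apart, since knockout replicate 3 was the only female knockout library. Exon length and GC content took 0.712% of the variance of its deviation. A stronger effect of the genotype in this animal cannot be told apart from other sources, since knockout replicate 3 minus 2 correlated with knockout replicate 1 minus wildtype at r = 0.11 and the reverse pairing gave -0.14. Differences in dissection, which could alter epicardium and blood, were not tested.

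DNA replication genes were lower in knockout hearts. An older stage of the knockouts would lower genes that decline with age and raise genes that rise with it, but the 13 of the first kind had a median log2 fold change of -0.02 (-0.99 to 0.34), and the 15 of the second a median of -0.07 with 3 above 0. These lists alone cannot decide on an older stage, since members of both went both ways, with a lower quartile of -0.15 in the first. Some, such as H19 (0.723) and Acaa2 (0.745 reads per base of exon), lay near the cap. The design text compares the knockouts with littermate controls, which would share an age within a litter. The test assumed that fewer endothelial cells and fibroblasts would lower their markers by about as much as the DNA replication genes, whose median was -0.51. The medians of the 2 marker lists were 0.15 and 0.07 (SD 0.32 and 0.33 over genes), which gives no sign of a general loss of these cells. How much of the DNA replication signal came from these cells is not known, and the markers cannot show whether fewer of them divided. Other biological explanations were not tested, and the call of the DNA replication list rests on a preset correlation (camera, adjusted p = 0.741 with an estimated correlation).

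Abundant genes seemed capped in these values. The mean of recovered reads per base of exon reached at most 0.925 over 20172 genes, 77 genes were above 0.5, and 1 gene in a single library reached 1.01. Removal of duplicate reads, which allows a single-end read about once per start position, may be the cause. If so, rises of abundant genes are understated, and falls can be understated or overstated. Undoing the cap under that assumption would move the log2 fold change of Nppb from 0.87 to 1.32, of Ankrd1 from 0.51 to 0.85, of Ccn2 from 0.99 to 1.29, of Myh7 from 0.25 to 0.45 and of Cdkn1a from 1.2 to 1.31, while Rbpms would move from -1.61 to -1.7 and Myh6 from -0.15 to -0.12. For Nppa (log2 0.09), the gene at 1.01 in knockout replicate 3, it has no solution, so its change stays open.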
